A study of Macaca fascicularis with 20 samples.

How the data were processed

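Small RNA was sequenced from laser-microdissected pieces of the fetal neocortex of the crab-eating macaque. Per the labels' protocols, a UV laser microscope was used to cut 7 regions. These were the ventricular zone (VZ), where radial glia divide along the ventricle, the outer subventricular zone (OSVZ), a germinal layer that is thick in primates, and the cortical plate (CP), where young neurons settle, each in areas 17 and 18 of the visual cortex. The OSVZ of area 17 was taken as an inner, apical sublayer (OSVZ_17int) and an outer, basal one (OSVZ_17ext). How a region was recognised in a section was not given in the sources used here. Per the labels' protocols, RNA was isolated with a Qiagen kit in the presence of DTT, and size-selected libraries were made for the SOLiD platform.

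The labels name 20 samples in 3 replicate sets, each set with its own embryonic day. The authors deposited read counts per miRNA name and arm, with 1 column for the 5p arm and 1 for the 3p arm of each library. The aligner, the genome build, the miRNA annotation and the treatment of reads that match several loci were not given in the sources used here, so arms of near-identical family members (the let-7 or miR-548 families, for example) may share reads. The columns name a region and an arm, and were assigned to the first set (embryonic day 80) or the second set (embryonic day 79) by how each table spells its regions and by which regions it holds. This gave 14 libraries, 2 per region. A further 12 value columns, of 6 libraries, have names that match no label and were not used, and 6 labelled samples, those of the third set, are not analysed here. The design had been written for 20 libraries in 3 sets and was fitted to 14 libraries in 2 sets. Whether the regions of a set came from 1 animal is not stated. With 2 libraries per region, p-values measure the spread between these libraries that is left once a difference shared by a whole set is taken out. This spread may be partly technical.

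The first table lists 861 names and the second 868, of which 828 are in both. Both tables hold only names with at least 10 counts in total. The 33 names of the first table alone held 0.00161% of its counts and the 40 names of the second alone 0.0043%. The 828 shared names gave 1656 arms. Library totals over these ran from 3603478 to 9517217 counts, with a median of 6729539. Counts of PCR-amplified reads without molecular identifiers are not independent molecules. Standard errors and intervals come from the spread between libraries, and do not cover an error that all libraries share.

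Arms were filtered with filterByExpr by region, which kept 1139 arms holding 99.99% of the counts and removed 517. Counts were scaled with TMM and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, on contrasts of the 7 region means with the replicate set as a block (6 residual degrees of freedom, 28.1 prior degrees of freedom). All libraries entered 1 fit, so every comparison shared its estimate of the spread. VZ and CP were means of both areas, and OSVZ was the mean of area 18 and of the mean of the area 17 sublayers. P-values were adjusted by the Benjamini-Hochberg method over the 1139 arms, and an arm was called at an adjusted p under 0.05. Differences are log2 values with standard errors (SE), and levels are TMM-scaled CPM, given as mean ± SD. The median biological coefficient of variation was 114% over all tested arms and 59.7% over the 379 arms with a mean of at least 10 CPM.

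The block was kept as in the design, which took the regions of a set to be related. As a check of the pairing, deviations from the region means correlated between libraries of the same set with a median r of 0.309 over 21 pairs of regions (0.0351 to 0.564, across arms, which are not independent), and 20 of 21 pairs were above 0.1.

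TMM, DESeq2 size factors and library totals place the median of all tested arms differently. The median log2 difference under the 3 scalings was -0.22, 0.023 and 0.21 for VZ against CP, -0.20, -0.045 and 0.035 for OSVZ against CP, and 0.12, 0.019 and -0.12 for OSVZ against VZ. It was 0.17, 0.072 and 0.13 for inner against outer OSVZ and -0.23, -0.19 and -0.46 for area 17 against area 18. Within zones, area 17 against area 18 gave -0.30, -0.19 and -0.69 in VZ, -0.057, -0.061 and -0.25 in OSVZ, and -0.21, -0.16 and -0.30 in CP.

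Arms named in the text were chosen by a rule fixed before the data were examined. It takes up to 10 higher and 10 lower arms with the largest log2 difference among called arms with a mean of at least 10 CPM and the same direction in both sets, or the 5 arms with the smallest p where fewer than 5 passed, and up to 4 members of a list. Arms named for another reason were chosen after their values were seen. The miRNA lists were fixed at the same time. They are neuronal, progenitor and radial glia, let-7 family, miR-17 clusters, miR-29 family, 14q32 imprinted cluster, C19MC cluster, miR-548 family and Xq27 clusters, and as markers of other cells or tissues erythroid, endothelial, myeloid and lymphoid, mesenchymal and mural, oligodendrocyte, choroid plexus and pigment epithelium, miR-34 family (with miR-449), and liver and muscle. Both arms of miR-338 are in the neuronal and the oligodendrocyte list. Lists with at least 3 tested members were tested with camera from limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over lists within a comparison. Camera compares a list with all other arms, and fry does not. With an estimated correlation, camera also takes the 6 residual degrees of freedom of the fit, fewer than at the preset. A call lost in that setting therefore need not mean that the arms of the list move together. An example is the myeloid and lymphoid list in VZ against CP. Its estimated correlation was -0.00683, under the preset 0.01, while its camera p rose from 0.0061 to 0.0276. Fry results are those of its test for a shift of a list in 1 direction. Its mixed test, for changes in either direction, passed for further lists. An example is the progenitor list (fry mixed adjusted p = 5.8e-08 for VZ against CP and 1.33e-06 for OSVZ against CP).

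The steps were tested on simulated counts with 200 of 1139 arms changed. The changed arms were all drawn from the 379 arms with a mean of at least 10 CPM. The recovered shares therefore hold for arms of that level, not for all tested arms. In 5 simulated sets, edgeR recovered 9.78%, 45% and 75.5% of changes of 1, 2 and 3 on the log2 scale for VZ against CP with 2.21% false calls, and 12%, 62.6% and 85.2% for OSVZ against CP with 3.42% false calls. At a change of 2 it recovered 63.1% for OSVZ against VZ, 18.9% for inner against outer OSVZ, 72.9% for area 17 against area 18, 19.2%, 34.4% and 24.2% for the area within VZ, OSVZ and CP, and 5.58% for the interaction. The share of false calls of DESeq2, from 1 simulated set per comparison, was between 8.22% and 19%, above the nominal level. In 10 simulated sets for VZ against CP, a lowered neuronal list was called each time by camera with either correlation and by fry. With no change, camera called 0 and fry 3 of 160 list tests. Simulated arms were drawn independently, so this cannot show how the tests behave for lists whose arms move together. The estimated correlation in the data for VZ against CP was 0.129 for the let-7 family and 0.335 for the erythroid list.

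The counts of called arms and the named arms were recomputed without the block, with DESeq2 size factors, with library totals, without the filter, with DESeq2 1.42.0 and without each library. Of the named arms, those named for the size of their difference or the smallest p were covered. Members named from the lists alone were not. Counts summed per set and zone were run for VZ against CP, OSVZ against CP and OSVZ against VZ, and counts summed per set, zone and area for area 17 against area 18. The list calls were recomputed with an estimated correlation and without the block. A further 9 alternatives were chosen after seeing the data. They left out the 2 VZ libraries that stand apart, left out 4 set-dependent arms, kept only arms with a mean of at least 10 CPM, kept names listed in 1 table, summed the arms of a name, and normalized each set separately. The filter looks at the smallest region, so with a library left out it kept 1309 to 1358 arms, and 1303 with the 2 VZ libraries left out. The other 3 alternatives therefore left out each library, the 2 VZ libraries (also for the lists, with camera) and the 4 arms on the same 1139 arms, less the 4 in the last. No coordinates are given, since the gene table at hand was not used for miRNA loci. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.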

Results

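Small RNA libraries of 7 laser-cut regions of the fetal macaque visual cortex were compared between germinal zones and the cortical plate, between germinal layers, and between areas 17 and 18, which differ later in life in the number of neurons they hold. Each region had 2 libraries, from embryonic day 80 (set 1) and day 79 (set 2), which gave 4 libraries of VZ, 6 of OSVZ and 4 of CP. Library totals were between 3603478 counts (OSVZ_18 replicate 2) and 9517217 counts (OSVZ_17ext replicate 1). The 5p arm of miR-125b, abundant in neural tissue, took 26.8% to 49.3% of the counts, and 5p arms together took 62.9% to 88.8%.

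Comparing VZ with CP asks which miRNAs mark dividing radial glia against young neurons. The arm miR-92b-3p, which restrains intermediate progenitors in the mouse cortex, was 5.64 ± 0.44 (SE) higher in VZ on the log2 scale, at 38830 ± 12520 CPM in VZ (n = 4), 18920 ± 4109 CPM in OSVZ (n = 6) and 786 ± 277 CPM in CP (n = 4). Its passenger arm miR-92b-5p was higher by 5.58 ± 0.49. Also higher in VZ were miR-887-3p (4.36 ± 0.40), miR-574-5p (4.87 ± 0.67) and miR-574-3p (2.88 ± 0.40) as well as miR-222-3p, a repressor of the cell cycle inhibitor p27 (3.12 ± 0.44). At the other end, miR-137-3p and miR-138-5p, both regulators of dendrites and synapses, were -5.05 ± 0.62 and -3.63 ± 0.39 in VZ against CP, with miR-138-5p at 326 ± 170 CPM in VZ and 4034 ± 1770 CPM in CP. Of the 1139 arms tested with edgeR, 30 were higher and 54 lower in VZ at an adjusted p under 0.05, where 243 had an unadjusted p under 0.05 against 57.0 by chance. All 84 had the same direction in both sets.

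The other arms that met the naming rule were, higher in VZ, miR-31-3p (6.08 ± 1.63), miR-605-5p (3.87 ± 1.03), miR-193a-5p (3.0 ± 0.58) and miR-155-5p, a miRNA of activated immune cells (2.92 ± 0.53). Lower in VZ were miR-876-3p (-6.20 ± 1.17), miR-4271-5p (-4.74 ± 0.78), miR-323b-3p (-4.46 ± 1.26), miR-433-5p (-4.29 ± 1.22), miR-204-5p, known from choroid plexus and pigment epithelium (-3.84 ± 0.46), miR-326-3p (-3.64 ± 0.44), miR-139-5p (-3.35 ± 0.39) and miR-598-3p (-3.16 ± 0.43). The value of miR-31-3p rests on few libraries, with 13, 0, 2472 and 50 counts in VZ, the highest in VZ_18 replicate 1, and 0, 0, 8 and 0 in CP. Its log2 ratio was 5.07 in set 1 and 2.32 in set 2. The size for miR-876-3p was unsteady too, from -7.78 to -3.62 over the alternative settings, at 5.84 ± 8.45 CPM in VZ and 72.8 ± 9.44 CPM in CP.

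Among the 31 tested arms of the neuronal list, 12 were lower in VZ, 0 were higher and 19 did not pass, and 17 were lower when adjusted over the list alone. Examples were miR-139-5p, miR-7-3p (-2.46 ± 0.38), miR-132-3p (-1.89 ± 0.42), an activity-regulated neuronal miRNA, and miR-218-5p, a motor neuron and interneuron miRNA (-1.70 ± 0.37). The list was lower as a group by camera (adjusted p = 1.8e-09, and adjusted p = 0.006 with an estimated correlation), with a median of -1.70. By contrast the abundant miR-9-5p, expressed in progenitors and neurons alike, was at 32880 CPM in VZ and 64480 CPM in CP without passing (-0.92 ± 0.51, adjusted p = 0.298). In the progenitor and radial glia list, 3 of 30 arms were higher (both arms of miR-92b, and the hypoxia-induced miR-210-3p at 1.49 ± 0.41), 1 was lower (miR-125a-5p, -1.30 ± 0.40) and 26 did not pass, with the same counts adjusted over the list alone and no call for the list (camera adjusted p = 0.118).

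The let-7 family, whose members accumulate as progenitors differentiate, did not move as 1 group. Of 18 arms, let-7i-5p (-2.53 ± 0.48), let-7g-5p (-1.99 ± 0.43) and let-7f-5p (-1.81 ± 0.44) were lower in VZ, let-7b-5p (1.39 ± 0.37) and let-7c-5p (2.01 ± 0.61) were higher, and 13 did not pass. Adjusted over the list alone, 2 were higher and 4 lower, and the camera adjusted p was 0.768. In the miR-29 family, which increases as neurons mature, miR-29a-3p was higher in VZ (2.46 ± 0.42, from 71.9 CPM in CP to 389 CPM in VZ) and 5 of 6 arms did not pass, with 4 higher adjusted over the list alone. That list was higher by camera (adjusted p = 0.0109), a call lost with an estimated correlation (adjusted p = 0.258). In the proliferation-linked miR-17 clusters, 1 of 20 arms passed, miR-17-3p, which was lower (-1.46 ± 0.43), also when adjusted over the list alone (camera adjusted p = 0.127). The 14q32 imprinted cluster, a large miRNA domain active in neurons, had 5 of 82 arms lower and 0 higher, also adjusted over the list alone, among them miR-487b-3p (-1.74 ± 0.43) and miR-376c-3p (-1.71 ± 0.43), without a call for the list (camera adjusted p = 0.537). By edgeR 0 arms were called among the 27 of C19MC, the 22 of the miR-548 family and the 19 of the Xq27 clusters. This held over all arms and adjusted over the list alone. Recovery was simulated only for arms with a mean of at least 10 CPM. For arms under that level, 0 calls do not show that they are unchanged.

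Markers of other cells were measured beside these groups. Of the 12 myeloid and lymphoid arms, miR-155-5p and miR-223-3p (2.29 ± 0.52) were higher in VZ, miR-342-3p was lower (-1.67 ± 0.37) and 9 did not pass, with 5 higher and 1 lower adjusted over the list alone. That list was higher by camera (adjusted p = 0.0326), which was lost with an estimated correlation (adjusted p = 0.221) and with 2 VZ libraries that stood apart left out on the same arms (adjusted p = 0.0909). In the mesenchymal and mural list, miR-214-3p was higher (1.53 ± 0.43) and miR-199b-5p lower (-2.29 ± 0.71) of 12 arms, also adjusted over the list alone. In the oligodendrocyte list, miR-338-3p (-2.37 ± 0.56) and miR-338-5p (-2.41 ± 0.54) were lower and miR-219-3p was higher (2.80 ± 0.72) of 4 arms, also adjusted over the list alone. In the choroid plexus and pigment epithelium list, miR-204-5p was lower and 2 of 3 arms did not pass, also adjusted over the list alone. The 4 erythroid, 8 miR-34 family, 7 liver and muscle and 2 endothelial arms had 0 calls by edgeR in either adjustment. None of these lists except myeloid and lymphoid passed by camera, and the endothelial list was too small for it. The fry test called the neuronal (adjusted p = 0.000107), miR-29 (0.0145), myeloid and lymphoid (0.0145) and choroid plexus lists (0.000107, camera adjusted p = 0.127) and no other. Of the VZ libraries, VZ_18 replicate 1 stood apart, with erythroid arms at a median of 2.84, miR-34 family arms at 2.55 and myeloid and lymphoid arms at 1.39 above the other VZ libraries on the log2 scale. With it and VZ_17 replicate 2 left out, 80 of the same 1139 arms were called between VZ and CP, 58 of them among the 84, and camera also called the miR-17 clusters (adjusted p = 0.000943) and the progenitor list (adjusted p = 0.000508) as higher. In the Xq27 clusters the median was below 0 while the mean and the camera direction were above 0.

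The count of 84 was 53 without the block, 172 with DESeq2 and 53 of the same arms without CP_17 replicate 2. With library totals the split turned from 30 higher and 54 lower to 37 higher and 32 lower. Among arms named for the size of their difference, 4 calls ended in some settings, with single libraries left out on the same arms. They were miR-31-3p (adjusted p = 0.108 without the block, 0.0507 with DESeq2, 0.0569 with arms of at least 10 CPM, 1 without VZ_17 replicate 1, 0.0902 without VZ_18 replicate 1 and 0.0846 without CP_17 replicate 1) and miR-605-5p (0.064 with counts summed per set and zone, 0.153 without CP_17 replicate 2 and 0.112 without CP_18 replicate 1). The others were miR-323b-3p (0.0607 without the block, 0.0655 with library totals, 0.101 without VZ_17 replicate 2 and VZ_18 replicate 1 together, and 0.0567 to 0.107 without VZ_17 replicate 2, VZ_18 replicate 1, CP_17 replicate 1, CP_17 replicate 2 or CP_18 replicate 1) and miR-433-5p (0.131 without the block, 0.0938 with library totals, 0.0506 with arms of at least 10 CPM, and 0.0954, 0.112 and 0.318 without VZ_18 replicate 2, CP_17 replicate 2 and CP_18 replicate 1).

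**Figure D1:**
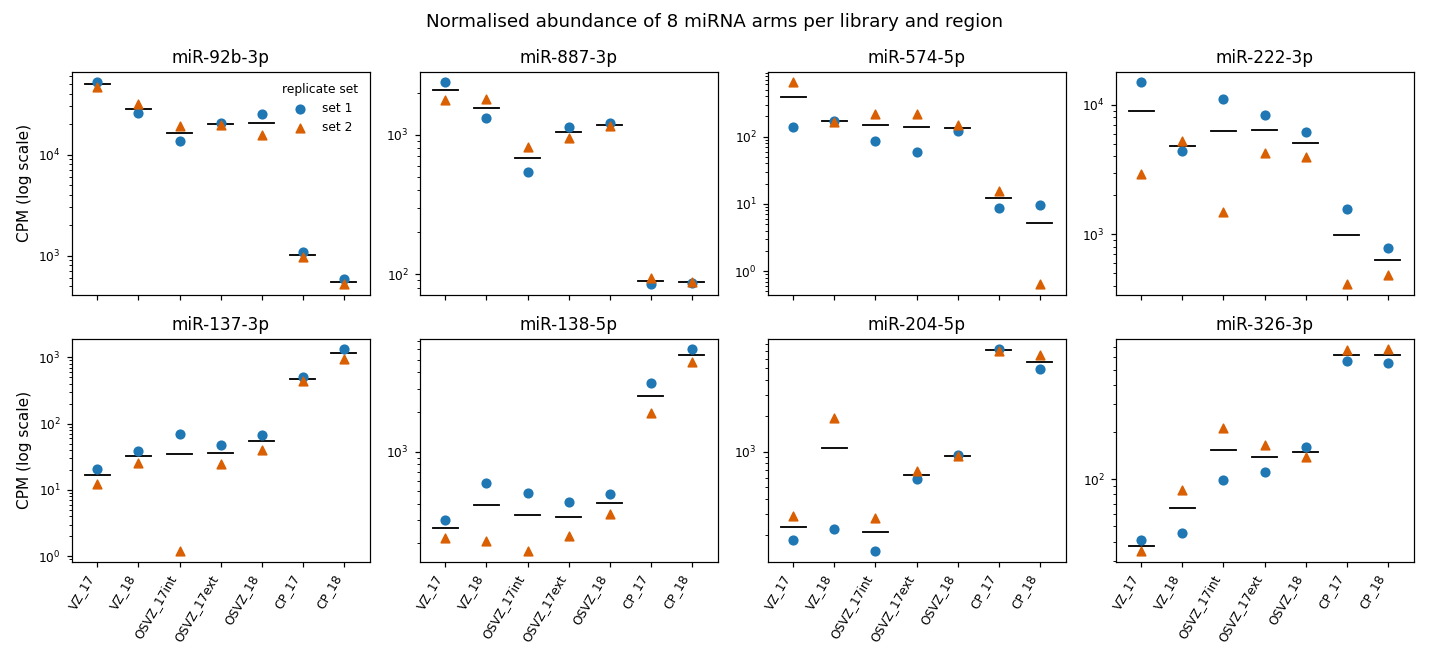
TMM-scaled abundance in CPM, on a log axis, of 8 miRNA arms in each library, by region and replicate set, with bars at the mean of the 2 libraries of a region. miR-92b-3p, miR-887-3p, miR-574-5p and miR-222-3p lay lower in CP than in VZ and OSVZ, by 5.64 for miR-92b-3p in VZ on the log2 scale, and miR-137-3p, miR-138-5p, miR-204-5p and miR-326-3p lay higher in CP.

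Comparing OSVZ with CP asks the same of the basal germinal layer. miR-92b-3p (4.68 ± 0.41), miR-92b-5p (4.37 ± 0.46), miR-574-5p (3.99 ± 0.63) and miR-887-3p (3.50 ± 0.38) were again higher, with miR-887-3p at 968 ± 256 CPM in OSVZ (n = 6) and 88.0 ± 4.13 CPM in CP (n = 4). miR-3613-5p was higher by 2.66 ± 0.44, at 403 ± 220 CPM in OSVZ and 53.0 ± 21.2 CPM in CP. In the other direction miR-137-3p (-4.27 ± 0.56), miR-204-5p (-3.46 ± 0.41), miR-138-5p (-3.42 ± 0.36) and miR-132-5p (-2.76 ± 0.48) were lower in OSVZ. With edgeR, 24 arms were higher and 48 lower at an adjusted p under 0.05, all 72 with the same direction in both sets, and 177 arms had an unadjusted p under 0.05.

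Further arms that met the naming rule were, higher in OSVZ, miR-31-3p (7.10 ± 1.64), miR-193a-5p (3.01 ± 0.56), miR-222-3p (2.85 ± 0.43), miR-942-5p (2.80 ± 0.63) and miR-877-5p, a mirtron processed by splicing (2.64 ± 0.73). Lower were miR-876-3p (-5.06 ± 0.995), miR-323b-3p (-4.02 ± 1.16), miR-598-3p (-3.04 ± 0.39), miR-628-5p (-2.81 ± 0.50), miR-338-5p (-2.72 ± 0.50) and miR-338-3p (-2.65 ± 0.51). The size of the difference of miR-31-3p was unsteady, at 2.65 in set 1 and 3.60 in set 2 alone, with means of 7.16 CPM in OSVZ and 0.443 CPM in CP, where 3 of 4 libraries had 0 counts.

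Of the 31 neuronal arms, 15 were lower in OSVZ, 0 higher and 16 did not pass, with 18 lower adjusted over the list alone. miR-129-3p (-2.32 ± 0.34), miR-139-5p (-2.25 ± 0.34) and miR-218-5p (-2.24 ± 0.34) were among them. The list was lower by camera (adjusted p = 4.87e-15, and adjusted p = 0.00347 with an estimated correlation). In the progenitor and radial glia list, both arms of miR-92b were higher and 28 of 30 arms did not pass, with 4 higher and 1 lower adjusted over the list alone. The list was higher by camera (adjusted p = 0.00884), which was lost with an estimated correlation (adjusted p = 0.424). Of the 20 arms of the miR-17 clusters, 0 passed with edgeR, and miR-20b-5p (1.26 ± 0.40) and miR-25-3p (1.14 ± 0.38) were higher adjusted over the list alone. That list was higher by camera (adjusted p = 0.0499), again lost with an estimated correlation (adjusted p = 0.447). In the miR-29 family miR-29a-3p was higher (2.09 ± 0.40), 5 arms did not pass and 2 were higher adjusted over the list alone, and the list's call (camera adjusted p = 0.0479) was lost with an estimated correlation (adjusted p = 0.435).

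In the 14q32 imprinted cluster, 6 of 82 arms were lower in OSVZ and 0 higher, also adjusted over the list alone, including miR-376c-3p (-1.92 ± 0.40), miR-487b-3p (-1.88 ± 0.39) and miR-495-3p (-1.70 ± 0.44). The cluster was lower by camera (adjusted p = 0.0033), a call lost with an estimated correlation (adjusted p = 0.424). Of the let-7 arms, let-7f-5p (-1.79 ± 0.40), let-7g-5p (-1.68 ± 0.39) and let-7i-5p (-1.85 ± 0.44) were lower, let-7c-5p was higher (1.87 ± 0.59) and 14 did not pass, also adjusted over the list alone. Among markers of other cells, miR-155-5p was higher (2.41 ± 0.50) of 12 myeloid and lymphoid arms, with 2 higher and 1 lower adjusted over the list alone. miR-214-3p (1.71 ± 0.42) and the smooth muscle miRNA miR-145-5p (1.45 ± 0.37) were higher and miR-199b-5p (-2.38 ± 0.66) was lower of 12 mesenchymal and mural arms, also adjusted over the list alone. Both miR-338 arms were lower of 4 oligodendrocyte arms, with miR-219-3p (1.81 ± 0.68) added as higher over the list alone. miR-204-5p was lower of 3 choroid plexus and pigment epithelium arms, also adjusted over the list alone, and that list was lower by camera (adjusted p = 0.0137, and adjusted p = 0.202 with an estimated correlation). The other lists had 0 arms called with edgeR in either adjustment and no camera call. The fry test called the neuronal (adjusted p = 0.000409), choroid plexus (0.000409), 14q32 (0.034) and oligodendrocyte lists (0.034, camera adjusted p = 0.54) and no other. Median, mean and camera direction differed in sign for the mesenchymal and mural, miR-34 family and erythroid lists.

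Single settings moved the count of 72 to 129 with DESeq2, 41 with counts summed per set and zone and, on the same arms, 125 without VZ_18 replicate 1 and VZ_17 replicate 2, 44 without OSVZ_18 replicate 2 and 44 without CP_17 replicate 1. The split turned to 35 higher and 44 lower with DESeq2 size factors and 38 higher and 34 lower with library totals. Members named from the lists alone were not recomputed. With single libraries left out on the same arms unless said otherwise, calls that ended were those of miR-31-3p (adjusted p = 0.193 without the block and 1 without OSVZ_17int replicate 1), miR-942-5p (0.0608 without CP_17 replicate 2), miR-338-5p (0.0523 without OSVZ_18 replicate 2 with the filter run again) and miR-877-5p (0.405 without the block, 0.0774 with counts summed per set and zone, and 0.05, 0.139 and 0.163 without CP_17 replicate 1, CP_17 replicate 2 and CP_18 replicate 2). That of miR-323b-3p ended without the block (0.0625), with library totals (0.0685), with counts summed per set and zone (0.279) and without any 1 of the OSVZ_17int, OSVZ_18 and CP libraries (0.0539 to 0.205).

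Many arms were called in both comparisons with CP, with 21 higher in both germinal zones, 40 lower in both and 0 in opposite directions. Both comparisons share the 4 CP libraries. Independent lists of these sizes would share 0.632 higher and 2.28 lower arms. Over the 379 arms with a mean of at least 10 CPM, the log2 differences correlated with r = 0.846, across arms that are not independent, where the median of 20 simulated sets of unchanged groups against shared controls was 0.55, and their covariance was 1.81 where the simulated median was 0.338. With the controls split, VZ against CP_17 and OSVZ against CP_18 shared 11 higher and 23 lower arms (covariance 1.46), and VZ against CP_18 and OSVZ against CP_17 shared 11 higher and 26 lower (covariance 1.57).

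**Figure D2:**
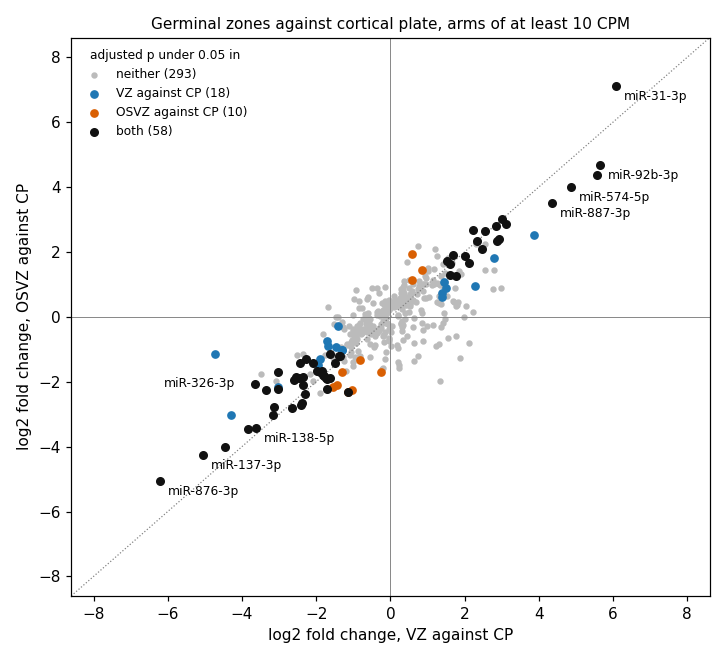
Log2 difference of VZ against CP (horizontal axis) and of OSVZ against CP (vertical axis) for 379 miRNA arms with a mean of at least 10 CPM; each point is 1 arm, the dotted line marks equal differences, and colors mark arms with an adjusted p under 0.05. Of these arms, 58 were called in both comparisons, 18 in VZ against CP alone and 10 in OSVZ against CP alone, with miR-92b-3p toward the upper right and miR-137-3p toward the lower left.

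Between the germinal layers, the direct comparison of OSVZ with VZ called 1 arm. miR-4271-5p was 3.61 ± 0.72 higher in OSVZ (adjusted p = 0.019), at 2.46 ± 2.37 CPM in VZ (n = 4), 34.0 ± 53.1 CPM in OSVZ (n = 6) and 128 ± 194 CPM in CP (n = 4). The next arms by p did not pass. They were miR-326-3p (1.57 ± 0.39), miR-335-3p, from an intron of the imprinted gene MEST (1.75 ± 0.46), miR-720-5p (1.53 ± 0.41), a name since assigned to a tRNA fragment, and miR-129-3p (-1.16 ± 0.33), with adjusted p between 0.173 and 0.254. miR-92b-3p, at 18920 CPM in OSVZ and 38830 CPM in VZ, did not pass either (-0.96 ± 0.34, adjusted p = 0.382).

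Adjusted over the list alone, miR-139-5p (1.11 ± 0.34) was higher and miR-129-3p and miR-129-5p (-1.43 ± 0.45) were lower in OSVZ among neuronal arms, and miR-335-3p was higher and miR-92b-5p (-1.21 ± 0.38) lower among progenitor arms. By camera, the miR-34 family of multiciliated cells was lower in OSVZ (median -1.62, adjusted p = 0.0396), which was lost with an estimated correlation (adjusted p = 0.275), and 0 of its 8 arms passed with edgeR. VZ_18 replicate 1, which stood apart, held 153 CPM of miR-34b-3p in that family, where the other VZ libraries had a mean of 25.4 CPM, and the call was lost with it and VZ_17 replicate 2 left out on the same arms (adjusted p = 0.0729). The 14q32 imprinted cluster was lower as a list (median -0.50, adjusted p = 0.0283, adjusted p = 0.394 with an estimated correlation, and adjusted p = 0.14 without these 2 libraries) with 0 of 82 arms passing. Without them camera called the let-7 (adjusted p = 0.0131) and miR-29 (0.0178) families as lower and C19MC (0.0178) as higher. The remaining lists had no camera call with all libraries and fry called none, and median, mean and camera direction differed in sign for the miR-17 clusters, the progenitor list and the choroid plexus list. At an unadjusted p under 0.05 there were 113 arms, and DESeq2 called 27. The call of miR-4271-5p ended without the block, with DESeq2 size factors, library totals, counts summed per set and zone, arms of at least 10 CPM or sets normalized separately (adjusted p = 0.0517 to 0.491), and, on the same arms, without VZ_18 replicate 1 (0.220), VZ_18 replicate 2 (0.106), OSVZ_18 replicate 2 (0.387) or CP_18 replicate 1 (0.178). On the same arms, leaving out VZ_17 replicate 1 gave 24 called arms.

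The sublayers of the OSVZ in area 17 were compared to ask whether its apical and basal parts differ. No arm passed (0 with edgeR, 46 at an unadjusted p under 0.05 and 2 with DESeq2, smallest adjusted p = 0.925). The arms with the smallest p were miR-299-5p (-3.20 ± 0.93, inner minus outer), let-7b-5p (-1.66 ± 0.53), miR-181a-5p (-1.76 ± 0.61), miR-4271-5p (3.02 ± 1.01) and miR-323b-3p, which had 0 and 0 counts in the inner and 36 and 37 counts in the outer libraries. The median SE was 0.762 over arms of at least 10 CPM with 2 libraries each, and 18.9% of simulated changes of 2 on the log2 scale were recovered. No list passed by camera (smallest adjusted p = 0.48, neuronal). Adjusted over the list alone, miR-204-5p (-1.69 ± 0.59) was lower among the choroid plexus arms and miR-211-3p, on few counts, higher, and signs of median, mean and test differed for the progenitor, C19MC, miR-548, erythroid, choroid plexus, and liver and muscle lists. On the same arms, 6 were called without VZ_18 replicate 1 and VZ_17 replicate 2, and 1 without OSVZ_17int replicate 1.

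Area 17 was set against area 18 over all zones. The 1 arm that passed was miR-4271-5p, which was -3.31 ± 0.56 in area 17 (adjusted p = 0.00148) and had the same direction in both sets. Arms with the next smallest p did not pass, with adjusted p between 0.125 and 0.156. They were miR-625-3p (-5.17 ± 1.25), miR-379-3p (-5.57 ± 1.40), miR-183-3p, of a sensory-organ cluster (-3.67 ± 0.97), and miR-31-3p (-4.26 ± 1.15), and VZ_18 replicate 1 held the highest count of each, 713, 388, 900 and 2472. A pair of lists was lower in area 17 by camera. These were the 14q32 imprinted cluster (median -0.72, adjusted p = 0.0302, and adjusted p = 0.455 with an estimated correlation), with 0 of 82 arms passing and 3 lower adjusted over the list alone (miR-136-3p, miR-379-3p and miR-433-5p), and the mesenchymal and mural list (median -1.02, adjusted p = 0.0302, and adjusted p = 0.373 with an estimated correlation; 0.0638 without the block), with 0 of 12 arms passing in either adjustment. The mesenchymal and mural arms lay at a median of 1.08 in VZ_18 replicate 1 and -1.11 in VZ_17 replicate 2 against the other VZ libraries. With both left out on the same arms neither list was called (adjusted p = 0.301 for each), and the miR-34 family (lower) and the miR-17 clusters (higher) were (adjusted p = 0.0437 for each). That fit has VZ_17 from the first set only and VZ_18 from the second only. Its VZ part therefore mixes area with set. Adjusted over the list alone, 1 arm each of the miR-34 family, choroid plexus and progenitor lists was lower, miR-34b-3p (-2.63 ± 0.88), miR-204-5p (-0.996 ± 0.32) and miR-183-3p. The remaining lists had no camera call, fry called the choroid plexus list alone (adjusted p = 0.0401, camera adjusted p = 0.129), and the camera direction differed in sign from both median and mean for the let-7, progenitor, C19MC and myeloid lists. There were 99 arms at an unadjusted p under 0.05 and 18 called by DESeq2. The call of miR-4271-5p ended without the block (adjusted p = 0.0522), with arms of at least 10 CPM only (0.0561), and, on the same arms, without OSVZ_18 replicate 2 (0.125) or CP_18 replicate 1 (0.282). There were 11 called arms without the filter and, on the same arms, 24 without VZ_17 replicate 1 and at most 6 without any other library.

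Within VZ, area 17 differed from area 18 in 2 arms. miR-652-3p was -3.49 ± 0.67 (adjusted p = 0.0105) and miR-1274b-5p, a name since assigned to a tRNA fragment, was -3.39 ± 0.73 (adjusted p = 0.0296) in VZ_17, both lower in each set. miR-652-3p had 1988 and 21 counts in VZ_17 and 58509 and 183 in VZ_18, in sets 1 and 2. miR-3164-5p (-3.20 ± 0.74, adjusted p = 0.0513), let-7f-3p (-2.41 ± 0.72, adjusted p = 0.298) and miR-876-3p (0 and 1 counts in VZ_17, 193 and 36 in VZ_18) did not pass. No list passed by camera (smallest adjusted p = 0.111, miR-34 family), though 4 of 8 miR-34 family arms (miR-34b and miR-34c, both arms), let-7f-3p and miR-204-5p (-1.97 ± 0.60) were lower adjusted over the list alone. The miR-34 family arms lay at a median of 2.55 in VZ_18 replicate 1 and -1.37 in VZ_17 replicate 2 against the other VZ libraries. With both left out on the same arms, the median of the family was -6.55. That leaves 1 library of VZ_17, from set 1, and 1 of VZ_18, from set 2, so area and set cannot be told apart there. At an unadjusted p under 0.05 there were 90 arms, and DESeq2 called 22. On the same arms, the call of miR-652-3p ended without VZ_18 replicate 1 (adjusted p = 0.343) and without it and VZ_17 replicate 2 (1), and that of miR-1274b-5p without VZ_18 replicate 1 (0.596), VZ_17 replicate 2 (0.205), both (1) or OSVZ_18 replicate 2 (0.0522). Without VZ_17 replicate 1, 26 of these arms were called. Both calls ended without the block (0.680 and 0.587), with arms of at least 10 CPM only and with sets normalized separately, and that of miR-1274b-5p with DESeq2 size factors (0.077).

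Within OSVZ, 0 arms passed between the areas with edgeR (29 at an unadjusted p under 0.05, 0 with DESeq2, smallest adjusted p = 0.477). The smallest p belonged to miR-4271-5p (-3.23 ± 0.83), miR-433-5p (-4.63 ± 1.49), miR-323b-3p (-4.55 ± 1.52), miR-204-5p (-1.40 ± 0.48) and miR-431-3p (-5.28 ± 1.80). The value of miR-433-5p turned to 1.05 without OSVZ_18 replicate 2, which held 231 of its counts. In CP, 0 arms passed with edgeR (36 at an unadjusted p under 0.05, 8 with DESeq2, smallest adjusted p = 0.122). There the smallest p belonged to miR-4271-5p (-4.77 ± 1.09), miR-205-5p, an epithelial miRNA (-4.94 ± 1.22), miR-93-5p of the miR-106b cluster (2.39 ± 0.64), miR-1260-5p (-2.03 ± 0.58) and miR-365-3p (-2.06 ± 0.60). No list passed by camera in OSVZ (smallest adjusted p = 0.0788, miR-17 clusters) or in CP (0.0674, 14q32 imprinted cluster), and adjusted over the list alone miR-204-5p was lower in OSVZ and miR-93-5p higher in CP. Across the within-zone area comparisons, camera direction, median or mean differed in sign for the progenitor and myeloid lists in VZ, let-7 in OSVZ, and the miR-34 family and liver and muscle lists in CP.

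The test of whether the area difference itself varied between VZ, OSVZ and CP called 1 arm, miR-652-3p (adjusted p = 0.0357), with 52 arms at an unadjusted p under 0.05 and 0 called by DESeq2. It was also lost without the block (adjusted p = 1), with DESeq2 size factors (0.0856), with arms of at least 10 CPM (0.694) and with sets normalized separately (0.191). On the same arms it was lost without VZ_18 replicate 1 (0.386), without it and VZ_17 replicate 2 (0.494), and without OSVZ_18 replicate 2 (0.0514), CP_17 replicate 2 (0.282) or CP_18 replicate 1 (0.0818). Without VZ_17 replicate 1, 16 of these arms were called.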

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

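Of the tests below, the comparison of miR-652-3p with the other arms higher in set 1, the interval of the marker arms and the leave-outs on the same arms or of 2 VZ libraries were chosen after the result was seen. Over 105 groups of libraries, 6 had a library far from the others, where chance gives 5.25.

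In VZ, miR-574-5p was at 652 CPM in VZ_17 replicate 2 (138 to 174 in the other 3 libraries), miR-628-5p at 139 CPM in VZ_18 replicate 1 (16.6 to 20.3), and miR-9-5p took 0.479% of the counts of VZ_17 replicate 2 (4.35% to 4.88%). In CP, miR-31-3p was at 1.77 CPM in CP_18 replicate 1 and 0 in the others. In OSVZ, miR-137-3p was at 1.18 CPM in OSVZ_17int replicate 2 (24.7 to 69.6 in the other 5), and miR-433-5p at 43.2 CPM in OSVZ_18 replicate 2 (0 to 1.21).

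Beyond these arms, VZ_18 replicate 1 and VZ_17 replicate 2 stood apart from the other libraries. Thinned to 3603478 counts they had 383 and 348 arms with at least 100 counts, above the 310 of the highest of the other 12 libraries (OSVZ_17int replicate 2), which argues against depth, and at 1.05 and 1.08 on a scale from CP (0) to OSVZ (1) neither lay near CP, which argues against a CP library under a wrong label. RNA of other cell types stays open for VZ_18 replicate 1, where 52 marker arms lay 1.17 above the other VZ libraries (percentile 99.8 of random lists), led by erythroid (2.84, miR-451-5p at 193 against 43.3 CPM) and miR-34 family arms (2.55). Those other libraries include VZ_17 replicate 2, whose marker arms lay low (-0.579), which raises the value of 1.17. They also include libraries of set 2, and no adjustment was made for the set. The lists moved apart, though, with choroid plexus arms at -0.605, and the most abundant myeloid and mural arms were not higher (miR-342-3p at 6270 against 6920 CPM, miR-145-5p at 546 against 1470 CPM), so that 1 rise of every other cell type alike is not what was seen. In VZ_17 replicate 2 the marker arms lay at -0.579 (interval -1.1 to -0.0103, arms taken as independent, against 0.214 at the 90th percentile of random lists). The libraries it was set against include VZ_18 replicate 1, whose marker arms lay high, which lowers this value. The test therefore cannot decide on RNA of all these cell types as 1 group there. Single types stay open as well (erythroid arms at 0.566, miR-342-3p at 7550 against 6500 CPM, miR-145-5p at 1690 against 1090 CPM). The difference of area, set or animal was not tested as a biological explanation.

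The area difference of miR-652-3p varied between the zones (adjusted p = 0.0357, edgeR) in the fit of all libraries. DESeq2 called 0 arms, and the call ended without the block (adjusted p = 1), without VZ_18 replicate 1 (0.0802, and 0.386 on the same arms) and without it and VZ_17 replicate 2 (0.355, and 0.494 on the same arms). The other 38 arms higher in set 1 had a median of -0.183 between VZ_17 and VZ_18 in that set (percentile 21.9 of random lists) and of -0.59 in set 2 (percentile 6.64), and miR-3164-5p, also higher in set 1, was at 1545 CPM in VZ_17 and 5226 CPM in VZ_18 of set 1, so the same source for its area difference stays open. Whether the other arm shares it cannot be told apart, since miR-652-5p, at 0.948 CPM, had a difference of 0.75 with an interval from -5.71 to 7.21. A difference between the areas in VZ stays open as well, with 2 libraries each, of which VZ_18 replicate 1 and VZ_17 replicate 2 are those that stood apart.

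Names listed in only 1 of the 2 tables entered no comparison, the most abundant being miR-3163 with 79 counts in the first and miR-548o with 230 counts in the second.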

How the results depend on the processing

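The alternatives that left out 2 VZ libraries or 4 set-dependent arms, kept arms of at least 10 CPM, normalized the sets separately, kept names of either table, summed arms, or left out libraries on the same arms were chosen after seeing the data. Of 44 called named results, 31 stayed called in every setting that gave a test and 13 were lost in at least 1, with 1785 of 1888 values the same. The values without a replicate set, counted among these, compare only the sign. For called arms the naming rule had already required that sign, so those values could only be the same. Over all 70 named results, 2713 of 2983 values were the same, 103 weaker, 164 stronger and 3 reversed. These results are the arms named for the size of their difference or the smallest p, without members named from the lists alone. The reversed result was miR-433-5p in area in OSVZ. It ran from -6.08 (without OSVZ_17ext replicate 2) to 1.05 (without OSVZ_18 replicate 2, and 0.97 on the same arms), and was 0.64 without replicate 2, since OSVZ_18 replicate 2 held 231 of its counts.

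Without the replicate block, the calls were 53 for VZ against CP and 0 for OSVZ against VZ, area 17 against area 18, area in VZ and the interaction. DESeq2 size factors gave 0 for OSVZ against VZ, 1 for area in VZ and 0 for the interaction, and library totals 0 for OSVZ against VZ. No filter gave 11 for area 17 against area 18, 5 for area in VZ and 3 for area in CP. The DESeq2 test gave 172 for VZ against CP, 129 for OSVZ against CP, 27 for OSVZ against VZ, 2 for OSVZ17 inner against outer, 18 for area 17 against area 18, 22 for area in VZ, 8 for area in CP and 0 for the interaction. Counts summed per set and zone with replicate block gave 41 for OSVZ against CP and 0 for OSVZ against VZ, from fewer libraries. With the 2 VZ libraries that stand apart left out, there were 120 for OSVZ against CP (all 72 among them), 2 for OSVZ against VZ, 3 for inner against outer, 3 for area 17 against area 18, 0 for area in VZ, 1 for area in OSVZ and 3 for area in CP. On the same arms these were 125 (all 72 among them), 2, 6, 3, 0, 1 and 3. With 4 set-dependent arms left out, of which miR-652-3p is 1, area in VZ gave 0 (1 on the same arms) and the interaction 0 (also on the same arms). A mean of at least 10 CPM gave 0 for OSVZ against VZ, area 17 against area 18, area in VZ and the interaction. Replicate sets normalized separately gave 0 for OSVZ against VZ, area in VZ and the interaction. The miRNA lists had 13 calls of 128, 2 with an estimated correlation, both of the neuronal list, and 16 with the 2 VZ libraries left out on the same arms, 8 of them among the 13. Where no cause is given, the cause was not tested.

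Without 1 library each, the filter kept 1309 to 1358 arms instead of 1139, so the counts with the filter run again mix the library with the filter, and those on the same arms change the library alone. With the filter run again and on the same arms, the calls ran from 59 to 112 and from 53 to 120 for VZ against CP, and from 43 to 92 and from 44 to 100 for OSVZ against CP. They ran from 0 to 16 and from 0 to 24 for OSVZ against VZ, from 0 to 21 and from 0 to 24 for area 17 against area 18, and from 0 to 23 and from 1 to 26 for area in VZ. For the interaction they ran from 0 to 15 and from 0 to 16. In both versions they ran from 0 to 1 for inner against outer (1 without OSVZ_17int replicate 1) and area in OSVZ, and from 0 to 3 for area in CP. The highest counts of the first 5 and of the interaction came without VZ_17 replicate 1 in both versions. For area 17 against area 18, each other library except OSVZ_18 replicate 2 gave 3 to 14 calls with the filter run again, and 0 to 6 on the same arms. A region left with 1 library was assumed to vary like the others. Leaving out a whole replicate set leaves no residual degrees of freedom, so it gave values and no calls, and the pseudocount alternatives did not apply to counts.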

Other observations

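Of the tests below, those of the set-dependent arms on precursors and on 1 shared source, and the count of partners once per name, were chosen after the result was seen.

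Most called arms had a partner arm that moved the same way. Of called arms with a tested partner, 75.7% (56 of 74) had such a partner between VZ and CP and 82.5% (52 of 63) between OSVZ and CP. Counted once per name, the shares were 73.1% (49 of 67, exact interval 60.9% to 83.2%) and 79.2% (42 of 53, 65.9% to 89.2%), where partners with signs drawn from all tested pairs would give 51.1% and 51.4%. Arms not called, the comparison fixed beforehand, had 55.4% and 57.7%, but their differences are smaller against their SE, which blurs their signs. Both arms were called for 7 names in VZ, among them miR-92b, miR-574 and miR-132, and for 10 in OSVZ, among them miR-138 and miR-129, with 0 in opposite directions. Moving the same way is not moving by the same amount. Of the 7 names in VZ, 6 had a tested ratio of 5p to 3p. Its log2 difference between VZ and CP was 2.43 ± 0.88 for miR-574 (adjusted p = 0.106 by limma), -1.14 ± 0.48 for miR-132 (0.153), -0.75 ± 0.72 for miR-181c, -0.71 ± 0.79 for miR-135b, -0.13 ± 0.47 for miR-92b and 0.054 ± 0.90 for miR-338 (0.502 to 0.992). None passed, so control of the precursor alone stays open.

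VZ may lie farther from CP than OSVZ does. Over 103 arms called between the mean of both germinal zones and CP, VZ lay a mean of 0.278 beyond OSVZ on the log2 scale, in 72 of 103 arms, with an exact permutation p = 0.05 over 100 relabellings within sets (highest other 0.322). The test does not pass and the question stays open.

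The ratio of the 5p arm to the 3p arm differed between VZ and CP for 1 of 101 names by limma, miR-296 (-2.70 ± 0.47, adjusted p = 0.0203), with 28 names at an unadjusted p under 0.05 against 5.05 by chance. The same test recovered 2.35% of simulated shifts of 2, so the number of names that differ stays open. The simulated arms of a name were drawn independently. Variation shared by both arms could not cancel in their ratio, so this share may be too low for the data.

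The neuronal miRNA miR-124-3p was at a mean of 0.215 CPM in VZ, 0.460 CPM in OSVZ and 1.96 CPM in CP, and did not pass (-4.61 ± 1.94, adjusted p = 0.165, edgeR). This arm is known to be abundant in neurons. How reads that match several loci were counted is not given in the sources used here, so the level is not read as an absence from CP.

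Between the replicate sets, 58 arms differed, 39 higher in set 1 and 19 higher in set 2, and 6 of them were among the calls of each germinal zone against CP. miR-3164-5p (694 to 5230 CPM in set 1, 0 to 5.37 in set 2), miR-34a-5p (11200 to 94400, 62.2 to 122), miR-652-3p and miR-130b-3p differed most, while miR-130b-5p went the other way (-2.42). A change of the whole precursor is argued against for the called arms as a group. The partner arm moved by a median of 0.0975 of the called arm's difference (interval -0.173 to 0.279, 44 arms). Single names stay open, since 25 of the 44 partners had the same sign and 6 were themselves called. Of the arms that differed most, miR-3164-5p had no tested partner, and that of miR-652-3p was at 0.948 CPM. For an effect of a few arms taking many counts, 53 of 54 other calls were kept with 4 arms left out. TMM limits the weight of such arms with and without them, so this result cannot decide on that effect. A source of RNA shared by the set 1 libraries is a candidate explanation, as the median rho of 35 arms with miR-3164-5p over its 7 libraries was 0.536 (percentile 100 of 10000 random lists). This rho cannot tell such a source from another factor that varies among these libraries. Among names numbered 3115 to 3202, 11 of 70 tested arms (15.7%) were higher in set 1, against 28 of 1069 others (2.62%). That range was not part of the design, and the reason for it was not tested. The embryonic day differs with the set, and whether the animal or the library preparation does is not stated, so these stay open as untested.

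Other splits of the same libraries, drawn within replicate sets, were fitted as well. For OSVZ against CP the real split called 97 arms in a fit of these libraries alone, 1 of 100 splits reached this, and the highest other called 4. The 1 split is the real one, and this share is the smallest that 100 splits can give. It argues against chance only as far as the libraries of a set can be exchanged, and whether they came from 1 animal is not stated. For VZ against CP the real split called 45 and the highest other 0, with 18 splits, too few for a share under 0.05. For OSVZ against VZ and for area 17 against area 18 the real split called 0 in such a fit and the highest others called 6 and 2. Any split calls at least 0, so that 100 of 100 splits did so decides nothing for either.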
